A study of Sus scrofa with 12 samples.

How the data were processed

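Messenger RNA of cultured primary cells from healthy pig aortic valves was sequenced in 12 libraries. Per the labels, 4 came from valve interstitial cells in growth medium (VIC_GM), 4 from interstitial cells kept for 8 days in osteogenic medium (VIC_OM) and 4 from valve endothelial cells in growth medium (VEC_GM). Interstitial cells are the fibroblast-like cells inside the valve leaflet and endothelial cells line its surface. The labels describe the 4 samples of each group as independent biological replicates; they do not give the animals, the composition of the osteogenic medium or the time in growth medium. Groups were taken from the sample titles.

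Per the labels' protocols, RNA was purified on columns and made into libraries with a kit that keeps the strand of the messenger RNA, and sequenced as read pairs. The submitters' processing notes name Trim Galore 0.6.4, Bowtie2 2.4.2, HISAT2 2.2.0, HTSeq 0.13.5 and edgeR without their roles, and builds of several species, of which Sscrofa11.1 is the pig. The strand setting of the counting is not given in the sources used here. The deposited table holds whole-number read counts per gene model and FPKM for each library, with Ensembl identifiers, coordinates, strand and symbols. The authors' FPKM values equal the count divided by gene length and by the library's total in the table, within a relative deviation of 2e-08, so they are scaled to total counts and carry no composition correction. Of 18437 gene models, 892 had 0 counts in all libraries. Symbols came from the table for 12306 models and from a name table for 654 more. Gene models of the table overlap often: 6191 overlap a model on the opposite strand, and an overlapping model is named beside each gene below that has one. Since the strand setting is not stated, values of such genes are uncertain, as are those of genes with near-identical copies. Counting on the opposite strand was not excluded. If it happened, values of overlapping models may be those of the opposite gene, and genes without such an overlap may be undercounted throughout. Genes with a symbol and no other model within 1 kb are called isolated.

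Counts were tested with edgeR 4.0.16 (TMM scaling, low-count filter, quasi-likelihood F test, R 4.3.3), with all 12 libraries in a single fit and 3 contrasts; 6905 genes were tested and the common biological coefficient of variation was 29.3%. P values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at adjusted p under 0.05. Values per gene are normalised counts in CPM, scaled to the TMM-corrected library size, as mean ± SD over 4 libraries. The ± of a log2 fold change is an approximate standard error (SE): the absolute log2 fold change divided by the square root of the F statistic. Where a group has few counts it can be too small, even below counting error, as for SNCG with 6 counts in VIC_GM. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound; with 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Between pairs of libraries of a group, squared deviations averaged 3.675 to 5.582 times what counting error gives. The intervals are therefore too narrow, and the bounds may be too tight.

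The 25 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Named genes are, for each contrast, the 10 with the highest and the 10 with the lowest log2 fold change among called genes with a symbol, a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups; up to 4 members per list with the smallest adjusted p; and fixed sentinel genes. Genes named for changing in both contrasts with VIC_GM are, in each set, the 10 whose smaller absolute log2 fold change of the 2 was largest. Some genes that these rules pick are not reported here. Other list members named in the text were chosen after their values were seen. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01, adjusted over 20 lists), again with an estimated correlation, and with fry. ALPL and MKI67 of the sentinels are not reported for lack of a model with these symbols; VWF and KDR lay below the count filter.

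To place VIC_OM between the other groups, each library was projected on the difference between VEC_GM and VIC_GM over genes differing by at least 1 on the log2 scale (prior count 2), with the VIC_GM libraries that define the axis kept apart from those placed on it, so that 0 stands for VIC_GM and 1 for VEC_GM; the groups were compared by an exact two-sided permutation test. Since both contrasts with VIC_GM share their controls, 20 simulated sets of unchanged groups were drawn at the VIC_GM means for all 12 libraries, and the 4 controls were split between the contrasts in 6 ways.

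On simulated counts for 6905 genes with the means of VIC_GM, made for VIC_OM against VIC_GM, edgeR recovered 12% of 50 genes changed 1.5-fold, 38% of those changed 2-fold, 64% of those changed 4-fold and 78% of those changed 8-fold, with 5.88% false calls. Alternatives were other scalings, DESeq2 1.42.0, other count filters, the groups compared alone, limma on log2 FPKM, a stricter threshold, the replicate number as a block and leaving out each library. A restriction to isolated genes was added after seeing the data.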

Results

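Gene expression was measured by strand-specific messenger RNA sequencing in 3 groups of primary porcine aortic valve cells with 4 libraries each: interstitial cells in growth medium (VIC_GM), interstitial cells after 8 days in osteogenic medium (VIC_OM) and endothelial cells in growth medium (VEC_GM). Total counts ranged from 1420816 to 1906979 per library. The means were 1794957 ± 46378 in VIC_GM, 1459452 ± 41126 in VIC_OM and 1812647 ± 66203 in VEC_GM (SD, n = 4). The median gene had 2 or 3 counts per library, so that genes of low abundance rest on few reads. The 10 models with most counts took 29.06% ± 0.23 of VIC_GM, 24.61% ± 0.28 of VIC_OM and 35.65% ± 0.71 of VEC_GM counts (SD, n = 4). Across genes, which are not independent replicates, libraries of a group correlated at a mean r of 0.93 in VIC_GM, 0.923 in VIC_OM and 0.929 in VEC_GM. VIC_GM correlated at 0.884 with VIC_OM and at 0.754 with VEC_GM, and VIC_OM at 0.72 with VEC_GM. All adjusted p values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

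**Figure D1:**
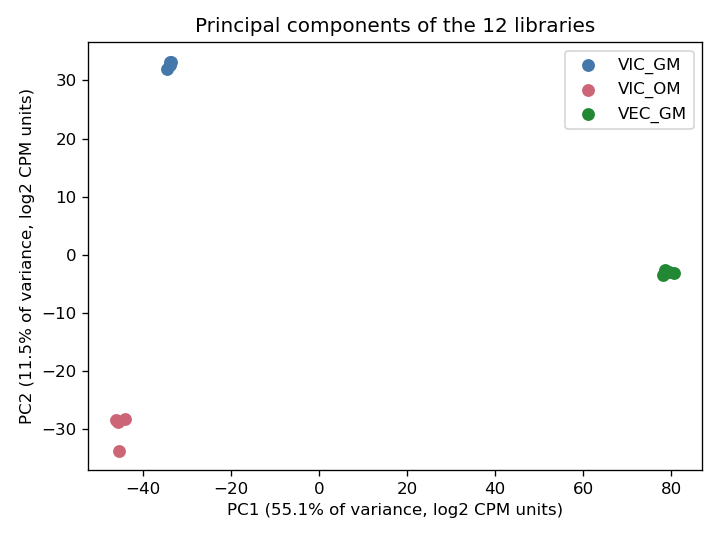
First and second principal component of log2 CPM, in percent of variance, for the 12 libraries; each point is 1 library, coloured by group. PC1 holds 55.1% of the variance and separates VEC_GM from both interstitial groups, and PC2 holds 11.5%.

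The comparison of endothelial with interstitial cells, both in growth medium, set the reference for cell identity. PECAM1, an endothelial adhesion molecule whose model overlaps MILR1 on the opposite strand, had 191 ± 34.3 CPM in VEC_GM and 0 counts in VIC_GM, at least 463-fold higher. CDH5, the cadherin of endothelial junctions, was at least 312-fold higher at 130 ± 8.66 CPM (SD, n = 4). EDN1, which encodes the vasoconstrictor endothelin, was at least 140-fold higher and the laminin gene LAMA1 at least 131-fold higher. In the other direction ACTA2, smooth muscle actin (overlapping STAMBPL1), was at least 901-fold lower in VEC_GM than its 434 ± 33.5 CPM in VIC_GM, and the collagen gene COL1A1 had 826 ± 34.8 CPM in VIC_GM against 0.488 ± 0.651 in VEC_GM, a ratio of 1720 with a counting interval of 588 to 8330.

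Of 19 tested members of the endothelial list, 14 were higher and 2 lower in VEC_GM (16 and 2 adjusted over the list alone; camera adjusted p = 1.33e-06). TIE1, an endothelial receptor, was at least 65.7-fold higher, the transcription factor SOX17 at least 58-fold higher and ECSCR at least 64.2-fold higher. The 2 lower members were CLEC14A, with a log2 fold change of -1.27 ± 0.44 (SE), and MMRN2, with -1.07 ± 0.32. The call of CLEC14A was lost without VEC_GM replicate 3 (log2 fold change -0.9, adjusted p = 0.103). The model of MMRN2 overlaps SNCG on the opposite strand, and the SNCG model was higher in VEC_GM by 11.14 ± 0.21. Which of these genes the reads came from cannot be told, so both directions are uncertain as statements about the genes. Of 21 tested members of the fibroblast and matrix list, 19 were lower and 1, VIM, higher (the same adjusted over the list alone; camera adjusted p = 5.28e-58). PRRX1, a mesenchymal transcription factor, was at least 180-fold lower, the surface marker THY1 at least 78.4-fold lower and PDGFRB at least 65.3-fold lower. The myofibroblast and contractile list had 9 of 13 members lower and 2 higher, CCN2 and TPM1 (camera adjusted p = 6.28e-05). Its 3 isolated genes alone gave a camera adjusted p of 0.56 in the other direction. The matrix protease and cross-linking list had 9 of 14 lower and 1, LOX, higher (camera adjusted p = 0.00749). The chondrogenic list (4 of 6 lower, 1 higher) and the mesenchymal transition regulators (3 of 5 lower, 1 higher) passed camera at an adjusted p of 0.0181 each. Both were lost at an adjusted p of 0.0637 with an estimated correlation. The other lists named here kept their call with it, with adjusted p of 0.0118, 0.000295, 0.0113 and 0.0409 in the order given. Counts of the last 4 lists were the same adjusted over the list alone.

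Other genes named by rule as higher in VEC_GM were STMN2, SPC25 (overlapping NOSTRIN), PXT1 (overlapping KCTD20) and PRR29, which overlaps ICAM2 on the opposite strand and rose by 8.64 ± 0.1 on the log2 scale. Those lower were CYP1B1, COL11A1 (overlapping an unnamed model), COL6A2, PRELP, FMOD, SFRP2, RBPJL (overlapping MATN4) and COL6A3. In all, 2470 of 6905 genes were called, 1162 higher and 1308 lower in VEC_GM, and 387 of 1319 when isolated genes were tested alone. Of the calls 47% were higher, against 36.1% by limma on log2(FPKM + 1), which differs from the edgeR fit in scaling, test, transformation and filter. The median log2 fold change was -0.04 over 6905 genes by edgeR and -0.18 over 8124 by limma.

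The comparison of interstitial cells in osteogenic and in growth medium addressed the response to osteogenic induction. The time at which VIC_GM was taken is not given in the sources used here, so that medium and time in culture are confounded in this comparison. The complement gene C7 (overlapping MROH2B) went from 0 counts in VIC_GM to 30.2 ± 6.8 CPM in VIC_OM, at least 71.9-fold higher. PLAT, tissue plasminogen activator, rose from 3.35 ± 2.44 to 131 ± 30.6 CPM (SD, n = 4; log2 fold change 5.27 ± 0.33, adjusted p = 6.81e-19). ACTA2 fell from 434 ± 33.5 to 49 ± 4.34 CPM (log2 fold change -3.14 ± 0.14, adjusted p = 2.54e-24). The glycoprotein gene GPNMB (overlapping IGF2BP3) fell from 40.6 ± 5.72 to 0.765 ± 1.53 CPM, and TNC, the matrix protein tenascin C, from 75.4 ± 20.2 to 3.83 ± 2.96 CPM. In all, 1039 of 6905 genes were called, 485 higher and 554 lower in VIC_OM, of which 274 and 268 changed at least 2-fold.

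Most contractile genes tested were lower in VIC_OM. Of 13 tested members of the myofibroblast and contractile list, 8 were lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 7.05e-12). Besides ACTA2, the fall was -3.14 ± 0.18 on the log2 scale for CCN2, a matrix-associated growth factor, -1.7 ± 0.17 for TAGLN, an actin-binding protein, and -0.88 ± 0.1 for TPM1. CNN1 (overlapping an unnamed model) was lower by -2.14 ± 0.61, a call lost without VIC_GM replicate 3 (log2 fold change -1.98, adjusted p = 0.0564). MYH11, smooth muscle myosin (overlapping NDE1), was the member that rose, by 2.01 ± 0.4. Of 21 members of the fibroblast and matrix list, 10 were higher and 11 not past the threshold (11 higher adjusted over the list alone; camera adjusted p = 2.27e-11). The proteoglycan genes DCN and LUM rose by 2.84 ± 0.35 and 2.09 ± 0.15, FBLN1 by 2.29 ± 0.24 and COL3A1 (overlapping COL5A2) by 2.31 ± 0.08. COL1A1 had 937 ± 19.9 CPM in VIC_OM against 826 ± 34.8 in VIC_GM (log2 fold change 0.18 ± 0.08, adjusted p = 0.149). It was called higher by DESeq2 (adjusted p = 0.0491), by edgeR with only the 2 groups fitted (0.0306) and by limma on log2(FPKM + 1) (0.0316). Outside the list, the matrix genes TNC and COL11A1 were lower, the latter by -0.82 ± 0.15.

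**Figure D2:**
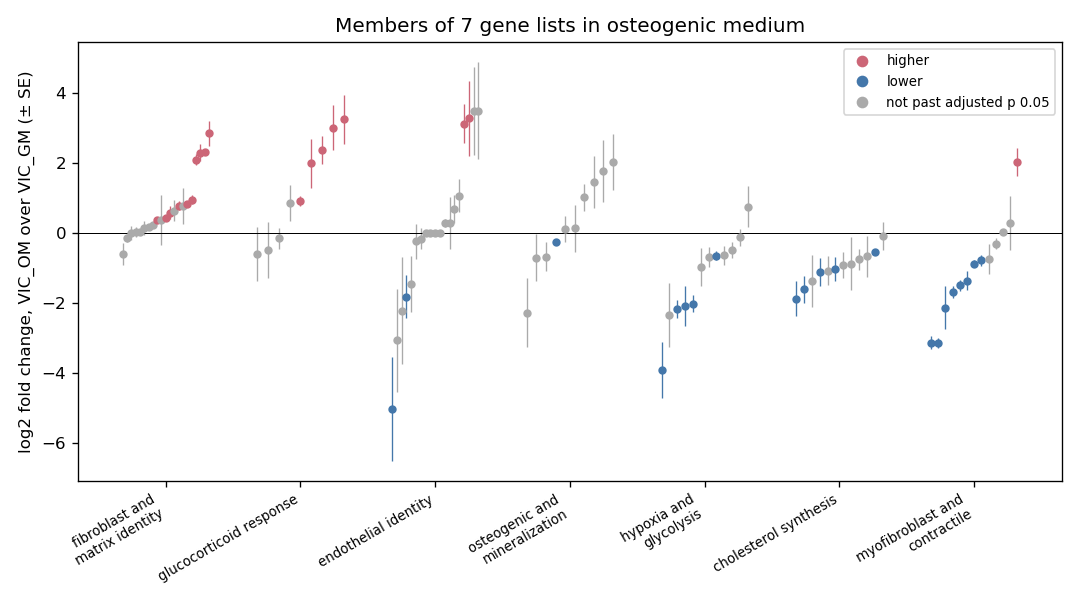
Log2 fold change of VIC_OM over VIC_GM, with its approximate standard error, for each tested member of 7 gene lists. Each point is 1 gene, red if higher, blue if lower and grey if not past an adjusted p of 0.05. In the fibroblast and matrix list 10 genes are higher, and in the contractile list 8 are lower.

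Genes of hypoxia and glycolysis were lower, 5 of 12 tested members with the rest not past the threshold (8 lower adjusted over the list alone; camera adjusted p = 0.00023). VEGFA, the vascular growth factor, fell by -2.18 ± 0.25, LDHA, lactate dehydrogenase, by -2.03 ± 0.24 and PDK1 by -3.92 ± 0.8. Of 12 cholesterol synthesis genes 5 were lower and the rest not past the threshold (8 lower adjusted over the list alone; camera adjusted p = 0.00393). DESeq2 called 3 of them and limma on log2(FPKM + 1) 2. INSIG1 was lower by -1.88 ± 0.5, a call lost by limma on log2(FPKM + 1) at an adjusted p of 0.0582. IDI1 (overlapping WDR37) fell by -1.61 ± 0.39 and FDFT1 (overlapping CTSB) by -0.55 ± 0.05. These 2 lists and the contractile and matrix lists held with an estimated correlation, at adjusted p of 0.0181, 0.0316, 0.000593 and 0.0224. Of 9 glucocorticoid response genes 5 were higher and 4 not past the threshold, with the same counts adjusted over the list alone. FKBP5, an induced chaperone, rose by 2.36 ± 0.4, the kinase gene SGK1 by 3.25 ± 0.7 and TSC22D3 by 3 ± 0.64. That list passed camera at an adjusted p of 0.00719 and was lost at an adjusted p of 0.0532 with an estimated correlation. The 10 genes of unfolded protein and amino acid stress had 3 higher, among them PSAT1 at 3.14 ± 0.52 and XBP1 at 1.2 ± 0.32 (4 higher adjusted over the list alone). The camera adjusted p was 0.0451. The list was lost at an adjusted p of 0.0935 with an estimated correlation, at 0.0587 without VIC_GM replicate 1 and 0.0591 without VIC_OM replicate 1. In the adipogenic list of 3, FASN, fatty acid synthase, fell by -2.74 ± 0.17, the same 1 call adjusted over the list alone. That list had a camera adjusted p of 0.00719, lost at an adjusted p of 0.0509 with an estimated correlation and at 0.218 with the replicate number as a block. Its median log2 fold change was -0.11, and 0.03 by log2(FPKM + 1).

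Of 10 tested genes of the osteogenic and mineralization list, 0 were higher and 1, BMP6, was lower by -0.26 ± 0.05 by edgeR. Its model overlaps TXNDC5, so the value may be that of the other gene if reads were counted on the opposite strand. The BMP6 call was lost by limma on log2(FPKM + 1) at an adjusted p of 0.0688. The counts were the same adjusted over the list alone (camera adjusted p = 0.923). At an unadjusted p under 0.05, 2 members were higher and 2 lower. DESeq2 called 0 higher and 1 lower, and limma on log2(FPKM + 1) 2 of 9 higher and 0 lower, RUNX2 and MGP. RUNX2, the osteoblast transcription factor (overlapping SUPT3H), had 28 ± 2.29 CPM in VIC_OM and 13.9 ± 4.01 in VIC_GM (SD, n = 4), a log2 fold change of 1.01 ± 0.39 with an adjusted p of 0.0753. MGP, matrix Gla protein, had 12 ± 8.2 and 2.9 ± 2.77 CPM, a log2 fold change of 2.02 ± 0.8 with an adjusted p of 0.0848. With only the 2 groups fitted, edgeR called RUNX2 higher (adjusted p = 0.0199) and MGP higher (0.0253), and MGP also passed without VIC_GM replicate 3 (0.0487). SPP1, osteopontin, had 0.446 ± 0.892 and 2.5 ± 2.06 CPM, 5.45 times less in VIC_OM (counting interval 1.59 to 28.9; adjusted p = 0.127). It was called lower without VIC_OM replicate 1 (log2 fold change -5.1, adjusted p = 0.0155) and without VIC_GM replicate 1 (-2.68, 0.0498).

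Other genes named by rule as higher in VIC_OM were CERKL (overlapping ITGA4), MROH2B, NRP1, AMCF-II, ANGPTL5 (overlapping CEP126), RN18S, a ribosomal RNA gene uncertain because of its copies, and TMEM59L, whose model overlaps another on the opposite strand. Those lower were WIF1, GPR17 (overlapping LIMS2), SMAP1 (overlapping B3GAT2), ACSS2 (overlapping GSS), PPFIBP2 and ZCCHC17 (overlapping FABP3, 7280 ± 498 CPM in VIC_GM and 589 ± 84.4 in VIC_OM). When isolated genes were tested alone, 119 of 1319 were called. Of the calls 46.7% were higher by edgeR and 67.2% by limma on log2(FPKM + 1), with medians of all genes tested of 0 and 0.12.

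Endothelial genes in VIC_OM were examined because the series concerns a possible passage of interstitial cells to an endothelial state. The list as a whole did not pass its test. Of 19 tested members, 2 were higher, 2 lower and 15 not past the threshold (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.759). FLI1, an endothelial and blood cell transcription factor, rose by 3.12 ± 0.56 (adjusted p = 2.3e-05) and kept its call with each library left out in turn. The remaining calls depended on which libraries were kept, and limma on log2(FPKM + 1) called 2 members higher and 0 lower. CD34 was lower, but its 17 counts in VIC_GM all came from VIC_GM replicate 1, without which its log2 fold change was 0 with an adjusted p of 1. FLT1, a receptor of VEGF, was higher by 3.27 ± 1.07 (adjusted p = 0.0271). Its adjusted p lay between 0.0635 and 0.107 when VIC_GM replicate 1, 3 or 4 or VIC_OM replicate 2, 3 or 4 was left out. NOS3, endothelial nitric oxide synthase, was lower by -1.82 ± 0.62 (adjusted p = 0.0369), with an adjusted p between 0.0688 and 0.141 without VIC_GM replicate 3 or 4 or VIC_OM replicate 2 or 4.

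The genes that marked VEC_GM most clearly stayed near 0 in VIC_OM. PECAM1 had 5 counts in the 4 VIC_OM libraries together, 0.409% of its VEC_GM level (95% counting interval 0.128% to 0.927%; adjusted p against VIC_GM = 0.0509). CDH5 also had 5, or 0.63% (0.19% to 1.38%; adjusted p = 0.0836), all in VIC_OM replicate 4. Without VIC_OM replicate 2, PECAM1 had an adjusted p of 0.0259 and CDH5 of 0.0491. TIE1, SOX17, ECSCR and EMCN had 0 counts in VIC_OM and in VIC_GM, which allows up to 2.08%, 2.36%, 2.13% and 4.45% of their VEC_GM level in VIC_OM. Not all members higher in VEC_GM lay so low. FLI1 reached 42.6% of its VEC_GM level in VIC_OM (4.68% in VIC_GM), and FLT1, with 27 counts in VEC_GM, 136% (12.5% in VIC_GM). ERG lay at 24.8% (29.4% in VIC_GM) and EGFL7 at 2.74% (8.06% in VIC_GM).

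**Figure D3:**
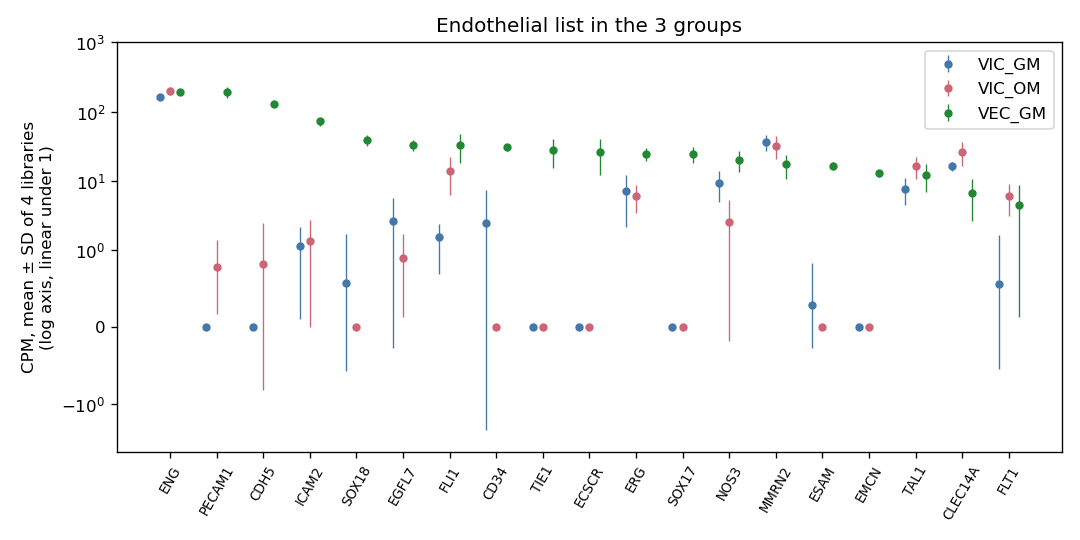
Mean CPM with SD over 4 libraries, on an axis that is logarithmic above 1 CPM, for the 19 tested genes of the endothelial list in the 3 groups. PECAM1 lies at 191 CPM in VEC_GM and at 0.782 CPM in VIC_OM.

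The comparison of VIC_OM with VEC_GM showed how far the induced interstitial cells differed from endothelial cells. ITIH3, a hyaluronan-binding protein gene (overlapping NEK4), was at least 987-fold higher in VIC_OM than in VEC_GM, at 475 ± 64.2 CPM, LUM at least 627-fold higher at 300 ± 54.2 CPM and SFRP1, a secreted Wnt inhibitor, at least 337-fold higher at 161 ± 25.3 CPM (SD, n = 4). DSP, desmoplakin, was at least 176-fold lower in VIC_OM than its 80.3 ± 12 CPM in VEC_GM and NPR3 at least 141-fold lower. Of 6905 genes, 2711 were called, 1412 higher and 1299 lower in VIC_OM, against 2470 between VEC_GM and VIC_GM.

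Of the endothelial list, 14 of 19 members were lower in VIC_OM than in VEC_GM and 2 higher (camera adjusted p = 8.43e-05), and of the fibroblast and matrix list 19 of 21 were higher and 1 lower (camera adjusted p = 2.65e-66). Both counts were the same adjusted over the list alone, and both lists held with an estimated correlation, at adjusted p of 0.038 and 0.000294. The matrix protease list had 8 of 14 higher and 3 lower (9 and 3 adjusted over the list alone) at a camera adjusted p of 0.0203, lost at an adjusted p of 0.0844 with an estimated correlation. Other genes named by rule as higher in VIC_OM were COL6A2, CYP1B1, COL1A1, CTSL, COL14A1, COL11A1 and FMOD, and as lower SNCG, GDF6 (overlapping an unnamed model), STMN2, FABP5, PRR29, SOX18 (overlapping TCEA2) and CD34. When isolated genes were tested alone, 415 of 1319 were called. Of the calls 52.1% were higher by edgeR and 70.8% by limma on log2(FPKM + 1), with medians of all genes tested of 0.04 and 0.29.

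Most genes that separated VEC_GM from VIC_GM by at least 2-fold were not called in osteogenic medium. Calls were still more frequent among them than over all genes tested, of which 15% were called. These sets were picked by calls in the same fit against the same controls, and genes called in a contrast may be easier to call in another. The higher frequency is therefore no evidence that genes of cell identity respond to the medium. Of 728 genes higher in VEC_GM, 96 were raised and 67 lowered in VIC_OM, and 77.6% were not called. Among the raised were EFNB2, an ephrin ligand of arterial endothelium, at 3.51 ± 0.47, PROCR, the protein C receptor, at 3.2 ± 0.68, and FLI1. NRP1, a co-receptor of VEGF, rose with a ratio of 29.3 (counting interval 9.69 to 145). The chemokine gene CXCL2, uncertain because it has near-identical relatives, rose with a ratio of 68.2 (11.8 to 2740). MTUS2 (overlapping SLC46A3) rose with a ratio of 14.7 (4.67 to 74.1) and SLC43A2 with one of 16.5 (5.3 to 83). NLRP6 rose by the same ratio, but its call as higher in VEC_GM was lost without VEC_GM replicate 4 (adjusted p = 0.0969). SEMA3G rose at least 5.13-fold with an adjusted p of 0.0215, which lay between 0.0517 and 0.188 without VIC_OM replicate 1 or without VIC_GM replicate 1, 2, 3 or 4. MRPL27 rose with a ratio of 10.3 (3.17 to 52.8) and an adjusted p of 0.0373, which lay between 0.0851 and 0.281 without VIC_GM replicate 1, 2 or 4 or VIC_OM replicate 2 or 3. By limma on log2(FPKM + 1), NRP1 and NLRP6 were not called as higher in VEC_GM (adjusted p = 0.218 and 0.156), nor NLRP6, SEMA3G and MRPL27 as raised in VIC_OM (0.0501, 0.343 and 0.121). Of 966 genes higher in VIC_GM, 145 were lowered and 129 raised in VIC_OM, and 71.6% were not called. The lowered included GPNMB, PPFIBP2, ACTA2, SFRP2, ZBTB33, S100A4, GALNT5, STAMBPL1 and SMAP1.

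Independent lists would give 51.1 raised and 58.4 lowered among the first set, and 77.5 lowered and 67.9 raised among the second. Raised against lowered differed in the first set by an exact two-sided binomial test over genes, which are not independent (p = 0.028). In the second set the exact two-sided binomial test of lowered against raised was not past the threshold (p = 0.365). With the VIC_GM libraries split between the contrasts, the mean counts were 54.5 raised and 55.3 lowered in the first set and 109 lowered and 98.5 raised in the second. The excess of raised genes was thus lost. Across genes, the effects of osteogenic medium and of cell type correlated at r = 0.1 (Spearman 0.144) with a covariance of 0.175. Unchanged simulated groups with shared controls gave a mean r of 0.492 and a covariance of 0.126, 0.0487 below that observed, and split controls gave 0.0476 and 0.097. On an axis where 0 stands for VIC_GM and 1 for VEC_GM, VIC_OM lay at 0.091 ± 0.006 and VIC_GM libraries kept apart from the axis at 0.069 ± 0.005 (SD, n = 4). The difference was 0.023, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries can give. Other measures, of a different kind, ran the other way. On PC1, fitted with VIC_OM included, VIC_OM lay at -46 to -44.1, farther from VEC_GM at 78 to 80.6 than VIC_GM at -34.6 to -33.5. The correlation of VIC_OM with VEC_GM was 0.72 against 0.754 for VIC_GM. Correlation takes in all changes, also those off the axis, so it can fall while VIC_OM moves along the axis.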

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

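A library was flagged when it lay far from the other 3 of its group, its gap to the nearest divided by the range of the group being above Dixon's 95% limit for 4. Of 353 groups of 4 libraries tested, over library measures, lists and genes named in the text, 37 were flagged. For continuous normal values chance flags about 1 in 20, here 17.6. A gene with counts in a single library of a group has a ratio of 1 by arithmetic and is always flagged. The 37 flags against 17.6 therefore cannot be read as an excess of outlying libraries. For single genes, only groups with more than 3 counts together were tested. No explanation was tested for these flags.

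The share of the gene with most counts was apart in VIC_GM replicate 1 (10.37% against a median of 10.69% in the others; ratio 0.909) and in VIC_OM replicate 1 (10.2% against a median of 9.68% in the others; ratio 0.891). The mean log2 CPM of the glucocorticoid response list was 4.185 in VIC_OM replicate 4 against a median of 4.552 (ratio 0.839). The mean log2 CPM of the adipogenic list was 5.71 in VIC_GM replicate 4 against a median of 6.223 (ratio 0.898). The mean log2 CPM of the mesenchymal transition regulators list was 3.924 in VEC_GM replicate 1 against a median of 3.308 (ratio 0.887). The mean log2 CPM of the leukocyte markers list was 4.621 in VEC_GM replicate 4 against a median of 4.395 (ratio 0.958). The mean log2 CPM of the pericyte and smooth muscle markers list was 3.922 in VIC_GM replicate 4 against a median of 4.651 (ratio 0.858).

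Some genes had counts in a single library of a group, with 0 in the other 3 and a ratio of 1. In VIC_GM replicate 1 these were CD34 (9.545 CPM), DSP (2.246 CPM), NPR3 (2.807 CPM) and SOX18 (2.246 CPM). In VIC_GM replicate 2 these were ANGPTL5 (2.19 CPM) and FLT1 (2.19 CPM). In VIC_GM replicate 3 these were FABP5 (3.217 CPM) and NOTCH1 (4.826 CPM). In VIC_OM replicate 1 this was WIF1 (2.345 CPM). In VIC_OM replicate 3 these were EDN1 (3.613 CPM), GPNMB (3.011 CPM) and SPC25 (2.409 CPM). In VIC_OM replicate 4 this was CDH5 (3.226 CPM). In VEC_GM replicate 2 this was GALNT5 (2.607 CPM).

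For other genes the CPM of a library is given with the median of the others and the ratio. VIC_GM replicate 1 was apart for FKBP5 (12.352 against 3.329, 0.846) and LOXL2 (129.133 against 96.888, 0.869). VIC_GM replicate 2 was apart for FMOD (104.552 against 126.326, 0.876). VIC_GM replicate 4 was apart for COX2 (865.501 against 1014.97, 0.92), FLI1 (2.774 against 1.095, 0.97) and GDF6 (4.438 against 0, 0.874). VIC_OM replicate 1 was apart for ZBTB33 (3.517 against 5.812, 0.914). VIC_OM replicate 4 was apart for SFRP2 (6.451 against 15.053, 0.947) and SLC43A2 (10.967 against 5.276, 0.862). VEC_GM replicate 1 was apart for BMP6 (24970.6 against 26385.3, 0.868), COL3A1 (0.57 against 1.955, 0.93) and COX1 (1222.06 against 1039.92, 0.942). VEC_GM replicate 2 was apart for NOTCH2 (1.303 against 0.646, 0.849). VEC_GM replicate 3 was apart for CLEC14A (0.646 against 8.853, 0.847) and LDHA (32.97 against 23.836, 0.95). VEC_GM replicate 4 was apart for ND6 (46910.3 against 28863.1, 0.894).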

How the results depend on the processing

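The restriction to isolated genes was chosen after seeing the data. The counts of changed genes stayed within 1.5 times under the other scalings, tools, filters and the replicate block, and at a log2 fold change of at least 1 VIC_OM against VIC_GM had 542. With each library left out the counts ranged from 916 to 974, 2343 to 2411 and 2604 to 2671 for VIC_OM against VIC_GM, VEC_GM against VIC_GM and VIC_OM against VEC_GM, and 65.8%, 75.5% and 77.2% of the calls remained in every such fit. Isolated genes, of which fewer were tested, gave 119, 387 and 415. Genes higher in VEC_GM and raised in VIC_OM numbered 55 with only the 2 groups fitted, 57 by limma on log2(FPKM + 1), 57 at an adjusted p under 0.01 and 16 among isolated genes, and 77 to 90 with a library left out. With VIC_GM split, which leaves no shared control but also fewer controls in each contrast, they were 54.5, below the 55.3 lowered, against 77.3 and 53.2 with the same 2 controls in both. Genes higher in VIC_GM and lowered in VIC_OM numbered 20 among isolated genes, 120 to 153 with a library left out, and 106 against 123 raised by log2(FPKM + 0.1), a reversal whose cause was not tested. The correlation of effects was 0.121 in isolated genes, 0.0476 with split controls and 0.0939 to 0.147 with a library left out, and the axis difference 0.02 to 0.028. For VIC_OM against VIC_GM, leaving out a library gave list adjusted p of 0.521 to 0.896 for the endothelial, 5.33e-13 to 3.27e-10 for the fibroblast and 0.834 to 0.982 for the osteogenic list. Among isolated genes, with fewer members, the matrix protease list was lower in VIC_OM than in VIC_GM (adjusted p = 0.0339), and the contractile list turned at 0.56 in VEC_GM against VIC_GM and at 0.0134 in VIC_OM against VEC_GM. Also among isolated genes, the interferon list (0.03) and the angiogenic ligands (0.0146) passed in VIC_OM against VIC_GM, and the angiogenic ligands (0.0174) in VEC_GM against VIC_GM. By fry, which does not compare a list with other genes, of 60 list results 26 that were not past camera passed, and 34 kept their side of the threshold. Of 7220 results of named genes under alternatives, 6877 were the same, 273 weaker, 69 stronger and 1 reversed: CD34, at -5.44 to 0 with a library left out, since its counts lay in 1 VIC_GM library.

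Replicate numbers did not pair the samples: over 2146 genes same-numbered libraries correlated at -0.037 to 0.078, and 4 of 12 correlated best with their own number. With the replicate number as a block 981, 2411 and 2644 genes were called. Among lists it ended the call of the adipogenic list in VIC_OM and, in VEC_GM against VIC_GM, it gave an adjusted p of 0.0202 for hypoxia and 0.0323 for cholesterol synthesis. Depth limits genes near the floor of 3 counts, and 12% of simulated 1.5-fold changes were recovered.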

Other observations

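The tests on mitochondrial genes, on models opposite endothelial genes, on single-copy genes, on list members below the count filter and on the removal of an endothelial share were chosen after the results were seen.

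Of 5 tested Notch genes, 2 were higher in VEC_GM than in VIC_GM, JAG2 at least 48.8-fold and NOTCH1 (overlapping SSNA1) by 4.33 ± 0.74 on the log2 scale, and 2 lower, NOTCH2 by -5.63 ± 0.46 and HEY2 by -3.58 ± 0.64, while in osteogenic medium edgeR called 0 of 5, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or by limma on log2(FPKM + 1). The 4 calls were the same adjusted over the list alone. All counts of NOTCH1 in VIC_GM came from VIC_GM replicate 3 (4.826 CPM). These counts work against its rise in VEC_GM, so the direction of that rise does not depend on them. The size of its change in both contrasts with VIC_GM does. The camera adjusted p was 0.935 in VEC_GM, downward with a median log2 fold change of 0.53, and 0.923 in osteogenic medium. The angiogenic ligands went both ways in VEC_GM, with PDGFB at least 51.5-fold higher and VEGFA lower by -3.25 ± 0.28 (3 higher and 5 lower of 9, the same adjusted over the list alone; camera adjusted p = 0.735, in the upward direction, with a median log2 fold change of -0.58). In osteogenic medium 1 of 9 was higher, EFNB2, and 1 lower, VEGFA (3 and 1 adjusted over the list alone; camera adjusted p = 0.682). Of 11 genes of the TGF-beta and BMP response, 1 was higher and 3 lower in VIC_OM, with INHBA at -2.53 ± 0.54 (2 and 3 adjusted over the list alone; camera adjusted p = 0.778). Among 14 matrix protease and cross-linking genes, ADAMTS1 and TIMP1 (overlapping SYN1) rose by 2.13 ± 0.47 and 2.65 ± 0.3 and PLOD2 and LOXL2 fell by -1.67 ± 0.36 and -1.22 ± 0.18 in osteogenic medium (3 higher and 4 lower, or 4 and 4 adjusted over the list alone; camera adjusted p = 0.923, upward, with a median of -0.17).

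In osteogenic medium, by edgeR, the inflammatory list had 1 of 6 higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.682). Of its 10 members below the count filter, edgeR without that filter called 1 higher, the cytokine gene CXCL8, with 1 count in VIC_GM and 62 in VIC_OM, and IL6 had 3 and 27 counts. The interferon list had 1 of 6 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.923). Of the chondrogenic list 2 of 6 were lower (2 adjusted over the list alone; camera adjusted p = 0.571), and of the mesenchymal transition regulators 1 of 5 was lower (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.923). By limma on log2(FPKM + 1), 1 chondrogenic gene and 0 mesenchymal transition regulators were lower. Pericyte and smooth muscle markers had 1 of 4 higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.96). Of 9 cell cycle genes edgeR called 0 (0 adjusted over the list alone; camera adjusted p = 0.923), with 2 higher at an unadjusted p under 0.05 and 0 by DESeq2 or limma on log2(FPKM + 1). The 12 members of that list below the count filter went the other way, with 116 counts together in VIC_GM and 21 in VIC_OM (16.1 ± 8.06 and 3.17 ± 2.11 CPM, SD, n = 4; exact two-sided permutation p = 0.0286, not adjusted over lists), and edgeR without the filter called 1 of them lower, CCNB1. Members below the filter had the same exact p, higher together in VIC_OM, in the glucocorticoid response and matrix protease lists, and lower together in the TGF-beta and hypoxia lists. Of 4 leukocyte markers edgeR called 0 (1 lower adjusted over the list alone; camera adjusted p = 0.923), with 1 lower at an unadjusted p under 0.05, 0 by DESeq2 and 1 higher by limma. Of 2 melanocyte markers edgeR called 0 (1 adjusted over the list alone), with 1 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma. The 1 lymphatic endothelial and the 1 red blood cell marker tested were not called by edgeR, DESeq2 or limma, the former with an unadjusted p under 0.05. In the TGF-beta, inflammatory and leukocyte lists camera pointed down and the mean log2 fold change was 0.03, 0.08 and 0.07, and in the cell cycle list it pointed up with a mean of -0.03. By fry, which tests a list without comparing it with other genes, 4 lists not past camera passed in osteogenic medium: chondrogenic (adjusted p = 0.000691), inflammatory (0.00399), TGF-beta and BMP response (0.0328), all downward, and angiogenic ligands (0.0226), upward. 0 epithelial and 0 cardiomyocyte markers passed the count filter.

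Several abundant genes carried few counts while a model on the opposite strand carried many. ND6, the mitochondrial protein gene on the minus strand, had 8.18 counts for each count of COX1, COX2 and COX3 on the plus strand together. A candidate explanation is that reads of the stranded kit were counted on the opposite strand. Its first test went against it: in 9 of 32 overlapping pairs with 1 ribosomal protein gene, 28.1%, the other model had more counts, where at least 80% had been predicted and a share under 50% was to exclude it. That bound was wrong by design, since pairs were matched by gene span without exon positions. In 0 of 32 was the overlap long enough to make shared exons certain, so the test leaves the explanation open. A bound set after the results were seen, more ND6 counts than COX1, COX2 and COX3 together, was met. Of 5 tested models opposite to endothelial list members, 80% were higher in VEC_GM against 16.8% of all tested models, which decides nothing, since SNCG and PRR29 had prompted the test and of the other 3 models 2 were higher (one-sided exact p = 0.0754). PRR29, opposite ICAM2, had 129 counts in VIC_GM, 88 in VIC_OM and 44814 in VEC_GM. ICAM2 itself had 446 counts in VEC_GM. In the same group ESAM had 103 against 9543 for the unnamed model opposite it, and MMRN2 had 107 against 12784 for SNCG. The other pairs went the other way, with 1206 for ENG against 209 for FPGS and 244 for SOX18 against 56 for TCEA2. Antisense transcripts counted on their own strand would leave abundant genes with many counts, whereas 38 ribosomal protein genes without an opposite model took 0.211% of counts, which discarded reads of pseudogenes could also lower, and 5 single-copy matrix and cytoskeleton genes took 0.354% of VIC_GM counts. If the explanation holds, values printed for models such as PRR29, SNCG, BMP6 and ZCCHC17 may be those of the gene on the opposite strand, and genes without an overlapping model may be undercounted.

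VIC_OM lay nearer to VEC_GM than VIC_GM did on the axis, by 0.023, but farther on PC1, by correlation (0.72 against 0.754) and by the number of genes called (2711 against 2470). Correlation and the number of calls take in differences off the axis too, and PC1 was fitted with VIC_OM included. These measures therefore do not contradict a small move along the axis. Endothelial cells among the VIC_OM cells would hardly move genes that are lower in VEC_GM. On those genes alone the difference was 0.022 (exact permutation p = 0.0286), which argues against such cells for these genes only. On genes higher in VEC_GM, which such cells could move, it was 0.023 (exact permutation p = 0.0286), and there the explanation stays open. The lower depth of VIC_OM is argued against, since after thinning all libraries to 1420816 counts the mean difference over 10 draws was 0.021. A response to the medium or to time in culture stays open as a possible explanation and was not tested.

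Among genes higher in VEC_GM, 96 were raised and 67 lowered in VIC_OM. Shared control libraries may account for that excess: with 2 VIC_GM libraries, raised minus lowered was larger by 27.5 genes when both contrasts used the same 2 than when they used different ones, 24.2 against -3.33. Endothelial cells among the VIC_OM cells stay open too as a candidate explanation. The largest share that PECAM1 and CDH5 allow by counting error alone, 0.871%, was taken from every gene of VIC_OM. This left 88 raised and 79 lowered, 9 more raised than lowered where there had been 29. That met the bound set for the explanation, under 50% of the excess, but removing counts of VEC_GM genes lowers the excess by construction, so the test does not support it.

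Other groupings of the libraries gave far fewer calls. Each of them mixes the 2 groups compared, which raises the spread and lowers the calls wherever the groups differ, so the size of the gap decides nothing. That the real grouping ranked highest of 35 argues against a random division of the libraries. It does not address other differences between the cultures. For each comparison 1 of 35 splits of its 8 libraries, the real one, gave as many genes: 1039 for VIC_OM against VIC_GM, where the highest other split gave 1, 2470 for VEC_GM against VIC_GM and 2711 for VIC_OM against VEC_GM, where the highest other gave 0.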
